A study of Homo sapiens with 3 samples.

How the data were processed

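Whole-genome bisulfite sequencing libraries were made from genomic DNA of 3 T-cell subsets. The subsets were flow sorted from digested, freshly resected germ cell tumour tissue, per the series' design text. Per the labels' protocols, DNA was bisulfite converted with a commercial kit and libraries were made after conversion by random priming and PCR amplification. Reads were aligned with BSMAP to hg19, per the submitters' processing notes. The version of the aligner, the methylation caller, read length, filters, strand merging and duplicate handling are not given in the sources used here, and duplicates left in the counts would make intervals too narrow.

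The authors deposited 1 file per library with 1 line per CpG. The deposited count of methylated reads is a whole number at every CpG. The deposited depth is an estimated count of informative reads, fractional at 1.63% of CpGs in PD1+Tim3+, 0.914% in PD1+Tim3- and 0.361% in PD1-Tim3-, and below the methylated count at 0.286%, 0.258% and 0.218%. The deposited methylation fraction equals the methylated count over this depth, limited to 1, to within 0.00462 in the 3 files, and was used only for this check. Unmethylated counts were computed here as depth minus methylated count, set to 0 where negative and rounded to whole numbers.

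The mean depth per listed autosomal CpG was 14.6 reads in PD1+Tim3+, 9.61 in PD1+Tim3- and 4.96 in PD1-Tim3-. PD1-Tim3- was thus both the shallowest and the most methylated library. CpGs with at least 5 reads in each library were kept, 43.8% of the autosomal CpGs listed in any library, so that all comparisons used the same CpGs. Only autosomes entered the comparisons. Levels were pooled as methylated over all read calls, with exact Clopper-Pearson 95% intervals.

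Bins of 100 kb with at least 20 CpGs were compared with no test, since bins are not replicates. Tiles of 1 kb with at least 3 CpGs were compared with a two-sided Fisher's exact test on read calls pooled over the tile, with Benjamini-Hochberg adjustment over the 1239388 tiles of each comparison. A tile was called where the adjusted p was under 0.05 and the levels differed by at least 20 percentage points. The median tile held 6 CpGs and 101 read calls in PD1+Tim3+, 68 in PD1+Tim3- and 43 in PD1-Tim3-. The test treats read calls as independent, which neighbouring CpGs on one read are not. Tile calls were therefore set beside a simulated draw in which all libraries had one level and CpGs within blocks of 200 bp shared every read, which overstates the sharing, and beside a draw with independent CpGs. Blocks do not cross tile borders, so these draws do not link adjacent tiles and understate their runs. Between the PD1+ subsets, tiles starting 2 kb from a called tile were therefore also measured, with a 95% t interval clustered by autosome, a test added after the data were examined. The independent draw gave at most 6 lower and 7 higher tiles in any comparison.

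Before the data were examined, the tests, the alternatives and the rule for named items were fixed. Gene annotation of hg19 was not used here, so the promoter and gene-list comparisons fixed in the design were not run, and the rule's fallback applied: the 5 longest runs of adjacent called tiles per direction and comparison are named by position. Where runs tied in length, those with the larger mean difference came first. Added after the data were examined were the grouping of called tiles with gaps of up to 5 kb into clusters, the splits by G-band and CpG number, the form of the simulated draws, and the tiles centred on the median or on their bin. G-bands of hg19 came from the table in circlize 0.4.16.

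To ask whether PD1+Tim3- was intermediate, tiles were called on alternating CpGs and measured on the others. Alternatives were coverage minimums of 3 and 10 reads, thinning to 5 reads, a difference of 30 points, CpGs at least 200 bp apart, unweighted means, tiles of 500 bp and at least 5 CpGs per tile. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

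The calling procedure was tested on simulated counts for all 1239388 tiles with 200 tiles lowered per comparison. For PD1+Tim3+ against PD1-Tim3-, 35.8% of tiles lowered by 30 points, 59.7% at 40 and 71.2% at 50 were recovered. For PD1+Tim3- against PD1-Tim3- the shares were 28.4%, 44.8% and 56.1%, and for PD1+Tim3+ against PD1+Tim3- 44.8%, 71.6% and 86.4%. At most 3 unchanged tiles were called and 0 tiles in the wrong direction. These counts were simulated with independent read calls, so they leave out the false calls that reads shared between CpGs would add. The recovery first required of this test at 50 points was not reached and was lowered, so isolated changes are detected with limited power.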

Results

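DNA methylation was measured by whole-genome bisulfite sequencing in T cells sorted directly from germ cell tumour tissue. Per the labels, all cells lacked CCR7, a homing receptor of naive and central memory T cells, and carried CD45RO, an isoform found on antigen-experienced T cells. They were divided by 2 inhibitory receptors of activated and exhausted T cells, PD1 and Tim3, into PD1+Tim3+, PD1+Tim3- and PD1-Tim3- subsets. The series title names CD8 T cells and their terminal differentiation, so the 3 comparisons between subsets ask how the methylome differs with these receptors. There was 1 library per subset, and the labels do not say whether the 3 libraries came from one tumour. No difference between subsets could therefore be set against a spread between replicates, and each test compares 2 libraries, not 2 conditions.

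The PD1+Tim3+ data listed 26265341 autosomal CpGs, with a mean depth of 14.6 reads. The PD1+Tim3- data listed 26045294 at 9.61 reads, and the PD1-Tim3- data 24595226 at 4.96 reads. The comparisons used the 11571652 autosomal CpGs with at least 5 reads in each library. At these CpGs the median depth was 18 reads in PD1+Tim3+, 12 in PD1+Tim3- and 7 in PD1-Tim3-. Sex chromosomes were not analysed here. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, since reads carry no molecular identifiers and neighbouring CpGs share reads.

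Both PD1+ subsets were less methylated than the PD1-Tim3- subset on every autosome. The pooled autosomal CpG methylation level was 71.8% in PD1+Tim3+, 72.5% in PD1+Tim3- and 78.8% in PD1-Tim3-. PD1+Tim3+ differed from PD1-Tim3- by -7.03 percentage points and PD1+Tim3- by -6.30, and in both comparisons all 22 autosomes were lower. Chromosome 18 showed the largest difference, -8.36 points in PD1+Tim3+ and -7.43 in PD1+Tim3-, and chromosome 19 the smallest, -4.49 and -3.88 points. Between the PD1+ subsets the difference was only -0.731 points, with PD1+Tim3+ lower on 21 of 22 autosomes and chromosome 21 at 0.135. The counting intervals of these levels were narrower than 0.1 points, while variation between libraries of one subset is unknown. PD1-Tim3- was also the shallowest library, and its difference from PD1+Tim3+ was 7.73 points at CpGs with 8 to 12 reads in each library.

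The lower level of the PD1+ subsets came with more CpGs at which only some reads were methylated. After each CpG was thinned to 5 reads in every library, 59.8% of CpGs had all 5 reads methylated in PD1-Tim3-, against 43.9% in PD1+Tim3+ and 46.1% in PD1+Tim3-. CpGs with 1 to 4 methylated reads made up 29.8% in PD1-Tim3-, 45.1% in PD1+Tim3+ and 43.1% in PD1+Tim3-. Such a count can also come from a highly methylated CpG. At full depth, which differed between libraries, CpGs at 20 to 80% made up 22.2%, 30.3% and 29.9% in the same order, a smaller gap. CpGs with no methylated read were similarly frequent, at 10.4%, 10.9% and 10.8%.

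Differences extended over broad domains. Of 26889 autosomal bins of 100 kb, 26624 were lower in PD1+Tim3+ than in PD1-Tim3-, and 26342 were lower in PD1+Tim3- than in PD1-Tim3-. The median bin level was 83.8% in PD1-Tim3-, 72.8% in PD1+Tim3+ and 73.6% in PD1+Tim3-. Bins lower by at least 10 points numbered 11641 in PD1+Tim3+ and 9743 in PD1+Tim3- against PD1-Tim3-, but 3 between the PD1+ subsets. PD1+Tim3+ was below PD1+Tim3- in 69.0% of bins, with a median difference of -0.723 points.

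**Figure D1:**
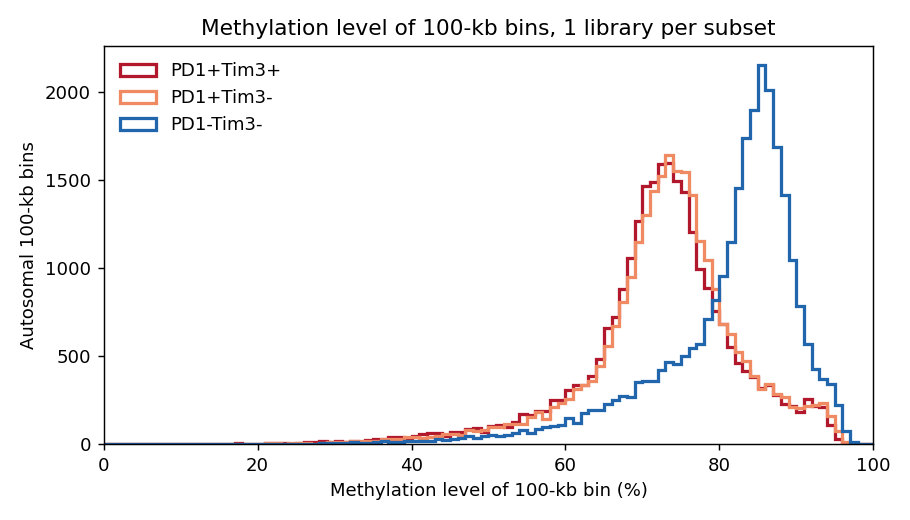
Histogram of the CpG methylation level (x axis, percent) of autosomal 100-kb bins (y axis, number of bins), 1 line per library. The PD1+Tim3+ and PD1+Tim3- lines nearly overlie, with medians of 72.8% and 73.6%, and the PD1-Tim3- line lies to their right with a median of 83.8%.

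Dark G-bands, the AT-rich and gene-poor part of the genome, differed most. Bins in the darkest class, gpos100, were lower in PD1+Tim3+ than in PD1-Tim3- by a mean of -11.4 points (SD across bins 3.83), and bins in light bands by -7.58 points (SD 4.09). PD1+Tim3- showed means of -10.3 and -6.86 points in the same classes. Among bins at 80 to 90% in PD1-Tim3-, the difference for PD1+Tim3+ was -12.3 points in gpos100 and -8.92 in light bands, and gpos100 was the lower on 17 of the 17 chromosomes with at least 20 bins of each class. This gap between the classes, -3.39 points, was -1.20 points when the bins were also matched to 500 to 800 CpGs, a check added after the values were seen. By CpG number, bins with at most 585 CpGs differed by -12.3 points and bins with at least 1305 CpGs by -5.41. Bins are not replicates, and their SDs describe the genome of these libraries only.

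**Figure D2:**
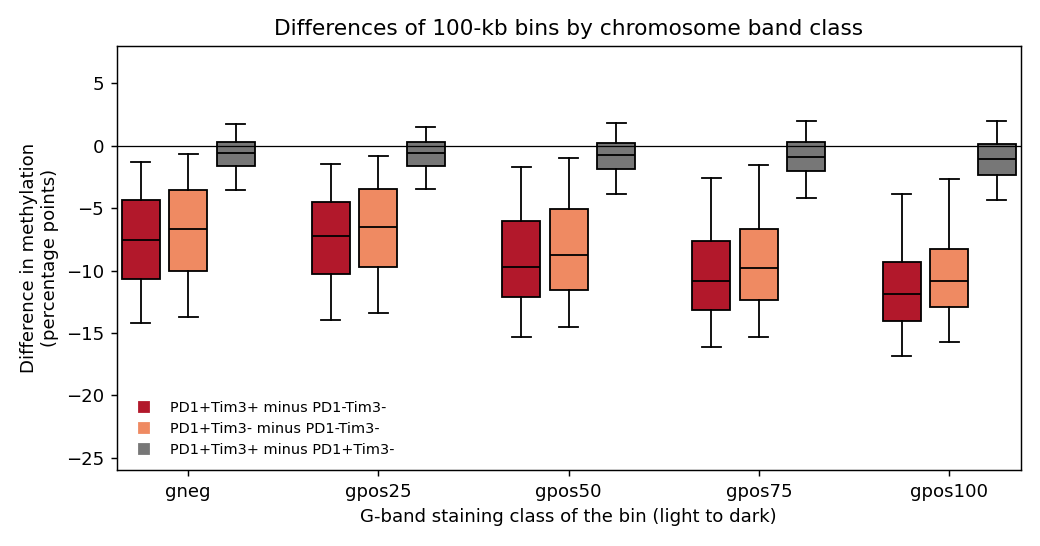
Difference in methylation level between 2 libraries (y axis, percentage points) of 100-kb bins by G-band staining class (x axis, light to dark). Boxes give quartiles and median and whiskers the 5th and 95th percentiles of bins. Mean differences from PD1-Tim3- are -7.58 points in gneg, -7.43 in gpos25 and -11.4 in gpos100 for PD1+Tim3+, and -6.86, -6.71 and -10.3 for PD1+Tim3-, while those between the PD1+ subsets stay between -0.713 and -1.11.

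CpG-dense sequence was an exception to the difference between subsets. The 29003 tiles of 1 kb that hold at least 50 CpGs had pooled levels of 27.1% in PD1+Tim3+, 27.9% in PD1+Tim3- and 26.4% in PD1-Tim3-. The 393964 tiles with fewer than 10 CpGs had levels of 75.3%, 75.6% and 85.6%. Tiles called lower in PD1+Tim3+ than in PD1-Tim3- made up 0.176% of the dense and 7.52% of the sparse tiles. Dense tiles had far lower levels and so less room to fall. The classes were not matched on level, so part of this contrast may come from that.

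At single regions, PD1+Tim3+ was mostly lower than PD1-Tim3-, and a small set of regions, 5q31.1 among them, was higher. Of 1239388 tiles of 1 kb, 66507 were lower and 2877 higher by at least 20 points. Part of this is the genome-wide difference. With the median tile difference taken off before the 20-point limit was applied, they numbered 39240 and 4735, and relative to their 100-kb bin 27834 and 3963. These scalings were chosen after the values were seen. Fisher's exact test still compared the unshifted counts, so these numbers are not free of the genome-wide difference. The region 39473001 to 39479000 on chromosome 22 (22q13.1, hg19) had a level of 25.7% in PD1+Tim3+ (23.4 to 28.0, 1457 read calls) and 72.4% in PD1-Tim3- (68.7 to 75.9, 624 read calls). The region 84632001 to 84638000 on chromosome 16 (16q24.1) had 31.6% against 70.3%, but its difference was only -18.8 points at the 10 CpGs with at least 10 reads in each library. Other long runs of lower tiles lay on chromosome 3 from 50443001 to 50449000 (3p21.31, 54.1% against 81.5%), on chromosome 1 from 16273001 to 16279000 (1p36.13, 40.4% against 67.1%) and on chromosome 3 from 5023001 to 5028000 (3p26.1, 37.4% against 71.6%).

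**Figure D3:**
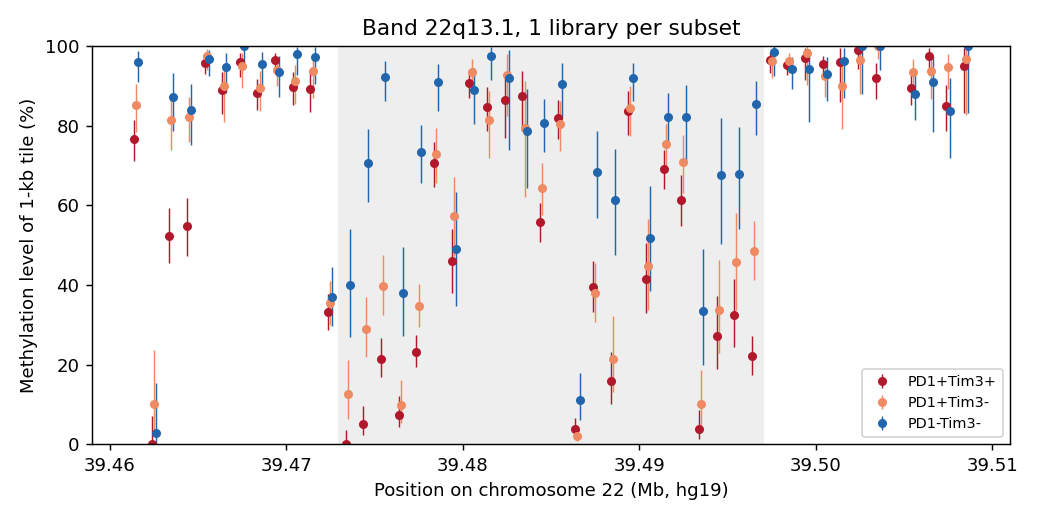
Methylation level (y axis, percent) of 1-kb tiles along chromosome 22 (x axis, Mb, hg19), 1 point per tile and library with exact 95% counting intervals. The shaded 24-kb cluster at 22q13.1 holds 14 tiles lower in PD1+Tim3+ than in PD1-Tim3-, with pooled levels of 44.3% in PD1+Tim3+, 50.7% in PD1+Tim3- and 72.5% in PD1-Tim3-.

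The higher region of PD1+Tim3+ with the most called tiles lay on chromosome 5 from 133452001 to 133474000 (5q31.1), where 17 of 21 tested tiles were higher. Regions at 15q13.3 and 1q42.12 were longer, at 29 and 24 kb against 22, but held 14 and 10 called tiles. This grouping of tiles across short gaps, like those shown at 22q13.1 and 8p12, was chosen after the values were seen. Its level was 62.1% in PD1+Tim3+ (60.7 to 63.6, 4442 read calls), 56.7% in PD1+Tim3- (54.9 to 58.6, 2766 read calls) and 29.9% in PD1-Tim3- (27.7 to 32.3, 1583 read calls). Within it, the run from 133459001 to 133463000 had 71.2% in PD1+Tim3+ against 33.2% in PD1-Tim3-, and the run from 133464001 to 133468000 had 65.0% against 25.4%. Further higher runs lay on chromosome 15 from 31649001 to 31653000 (15q13.3, 66.3% against 32.7%), chromosome 9 from 130734001 to 130738000 (9q34.11, 69.0% against 34.6%) and chromosome 11 from 118788001 to 118792000 (11q23.3, 57.9% against 26.1%). Gene annotation of hg19 was not used here, so regions are named by position and chromosome band.

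**Figure D4:**
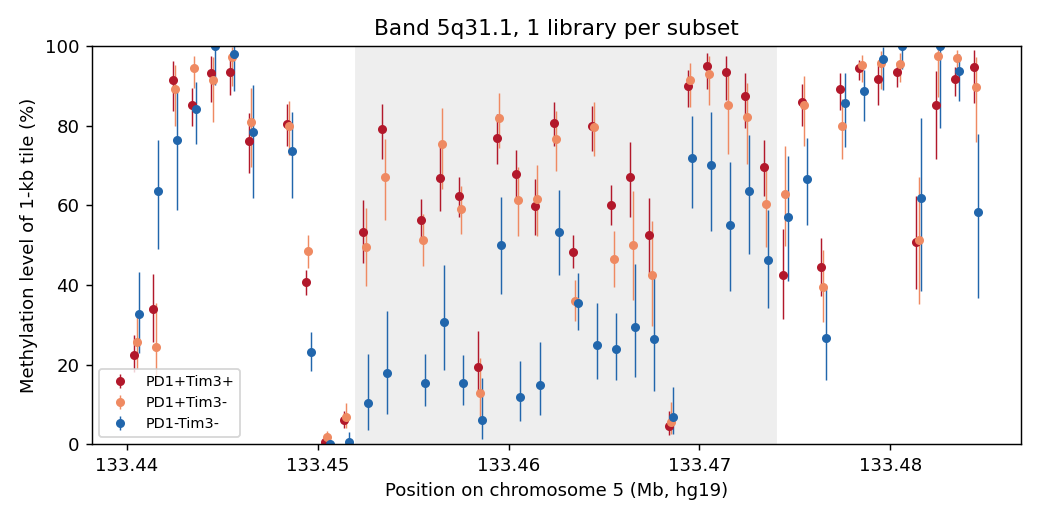
Methylation level (y axis, percent) of 1-kb tiles along chromosome 5 (x axis, Mb, hg19), 1 point per tile and library with exact 95% counting intervals. In the shaded 22-kb cluster at 5q31.1 the pooled level is 62.1% in PD1+Tim3+, 56.7% in PD1+Tim3- and 29.9% in PD1-Tim3-.

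Tiles were called by Fisher's exact test, two-sided, on pooled read calls with a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 points. When both libraries were drawn from one level with neighbouring CpGs sharing reads, 2338 tiles were lower and 4225 higher, and 6 and 5 with independent CpGs. The total of lower tiles stood far above both draws, and the total of higher tiles lay between them. Runs of at least 3 adjacent tiles numbered 262 lower and 13 higher, with 0 in the draws. The draws called far fewer lower tiles than the data, though more higher ones. They do not link adjacent tiles, so their 0 runs do not show that called tiles cluster in either direction. Each of the 30 longest runs over the 3 comparisons had a Fisher's exact p of 5.95e-09 or less. These p-values are not independent evidence, because runs were chosen by the same counts.

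PD1+Tim3- differed from PD1-Tim3- in much the same way, with 58805 tiles lower and 2734 higher, or 30496 and 3659 relative to their 100-kb bin. The run from 84632001 to 84639000 at 16q24.1 had a level of 32.7% in PD1+Tim3- (29.9 to 35.6, 1049 read calls) and 71.2% in PD1-Tim3- (67.3 to 74.8, 590 read calls). Lower runs also lay on chromosome 12 from 98911001 to 98916000 (12q23.1, 16.5% against 56.1%), chromosome 22 from 39473001 to 39478000 (22q13.1, 28.6% against 68.5%), chromosome 19 from 41258001 to 41263000 (19q13.2, 27.9% against 65.3%) and chromosome 2 from 203133001 to 203138000 (2q33.1, a difference of -33.5 points from 56.5% in PD1-Tim3-). Higher runs lay at 5q31.1 from 133459001 to 133463000 (70.6% against 33.2%) and from 133455001 to 133458000 (58.1% against 17.8%). The others were on chromosome 4 from 103535001 to 103538000 (4q24, 82.1% against 51.6%) and from 174427001 to 174430000 (4q34.1, 45.9% against 16.2%), and on chromosome 15 from 31650001 to 31653000 (15q13.3, 66.6% against 37.1%).

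The same test gave 2909 lower and 4060 higher tiles in the draws with shared reads and 6 and 7 with independent CpGs, so again only the lower total stood above both. Runs of at least 3 adjacent tiles numbered 228 lower and 7 higher, against 0 in the draws. The draws called far fewer lower tiles than the data, though more higher ones. Since they do not link adjacent tiles, their 0 runs do not show clustering in either direction.

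Tiles called in both comparisons with PD1-Tim3- overlapped in direction. Of the tiles lower in PD1+Tim3+, 28719, or 43.2%, were also lower in PD1+Tim3-, 1277 tiles were higher in both, and 0 were called in opposite directions. Independent lists of these sizes would share 3156 lower and 6.35 higher tiles, and draws with no effect shared 398 and 1133. Across tiles, the differences correlated at r = 0.751 against 0.645 in the draws, with a covariance of 86.7 against 54.8, a difference of 31.9. Both comparisons use the same PD1-Tim3- library, whose reads were not split between them, so part of the excess may come from it, and tiles are not independent replicates. Sharing it also makes opposite calls nearly impossible, since these would need a very large difference between the PD1+ subsets. For higher tiles the draws shared nearly as many, but out of 4225 and 4060 tiles, against 2877 and 2734 in the data. As a share, 44.4% of the tiles higher in PD1+Tim3+, the overlap thus exceeded that of the draws. The draws hold no genome-wide difference and overstate the sharing of reads, so the overlap does not settle whether both subsets differ there.

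Between the PD1+ subsets, PD1+Tim3+ was clearly lower at a few regions, of which 8p12 stood out. On chromosome 8 from 29202001 to 29206000, the level was 4.30% in PD1+Tim3+ (3.16 to 5.69, 1071 read calls), 33.2% in PD1+Tim3- (29.8 to 36.8, 717 read calls) and 63.0% in PD1-Tim3- (57.7 to 68.1, 349 read calls). The neighbouring run from 29198001 to 29201000 had 36.6%, 69.4% and 94.3% in the same order. On chromosome 11 from 76863001 to 76866000 (11q13.5), the levels were 14.3%, 48.0% and 59.1%. One run of at least 3 tiles was higher in PD1+Tim3+, on chromosome 17 from 30815001 to 30819000 (17q11.2), with 76.3%, 54.7% and 60.6%. Over all 765 lower tiles the mean levels were 47.2%, 76.3% and 72.0% (SD across tiles 19.9, 19.3 and 23.4). PD1-Tim3- lay above PD1+Tim3- in 37.8% of them, in 96.2% of the 734 higher tiles and in 76.2% of all tiles. Choosing tiles on the levels of the PD1+ subsets shifts these shares by itself, so they do not tell whether the order at the named regions is general.

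**Figure D5:**
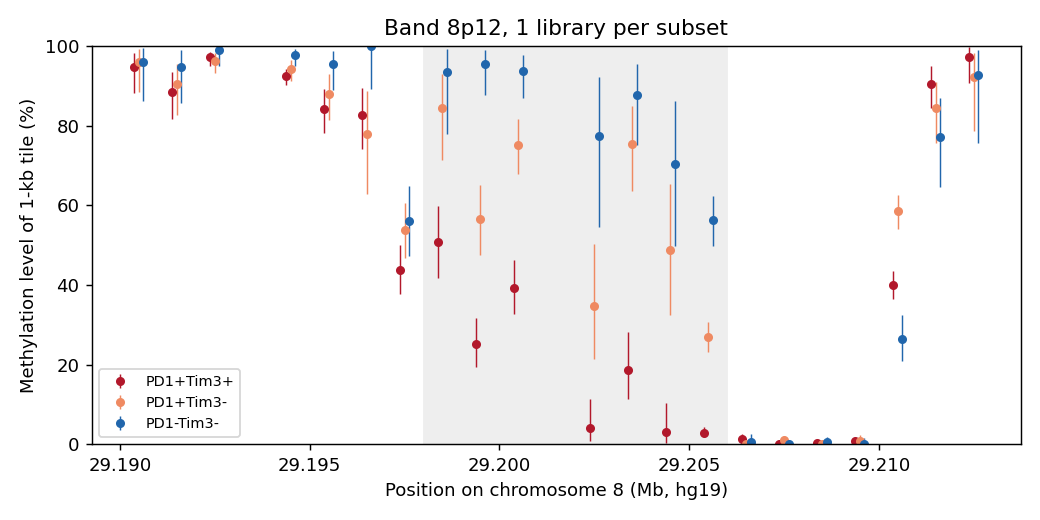
Methylation level (y axis, percent) of 1-kb tiles along chromosome 8 (x axis, Mb, hg19), 1 point per tile and library with exact 95% counting intervals. In the shaded 8-kb cluster at 8p12 all 7 tested tiles are lower in PD1+Tim3+ than in PD1+Tim3-, with pooled levels of 15.4% in PD1+Tim3+, 45.2% in PD1+Tim3- and 74.2% in PD1-Tim3-.

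Shorter runs of 2 tiles lay on chromosome 22 from 18633001 to 18635000 (22q11.21, 32.3%, 60.5% and 84.5% in PD1+Tim3+, PD1+Tim3- and PD1-Tim3-) and from 39463001 to 39465000 (22q13.1, 53.5%, 81.8% and 85.4%). Runs of 2 higher tiles lay on chromosome 8 from 126959001 to 126961000 (8q24.13, 70.5%, 17.4% and 19.4%), chromosome 7 from 130626001 to 130628000 (7q32.3, 62.7%, 20.8% and 63.6%), chromosome 5 from 73927001 to 73929000 (5q13.3, 52.9%, 14.1% and 59.0%) and chromosome 4 from 55952001 to 55954000 (4q12, 68.2%, 30.8% and 85.4%). Runs of at least 2 tiles numbered 7 lower among 754 runs and single tiles, against 4 among 2052 in the draws with shared reads, and 11 higher among 721, against 9 among 2858. These counts are too small to say whether a given run of 2 tiles exceeds sampling.

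In total 765 tiles were lower and 734 higher in PD1+Tim3+ than in PD1+Tim3- by Fisher's exact test, against 2056 and 2867 in draws from one level with shared reads and 3 and 4 in draws with independent CpGs. The totals lie between these draws, so how many single tiles exceed read sampling is not settled. With CpGs at least 200 bp apart, 0 of 500926 tiles passed by Fisher's exact test with adjustment. An unadjusted p under 0.05 was found for 24888, close to the share that this limit gives with no difference. The comparisons of PD1+Tim3+ and PD1+Tim3- with PD1-Tim3- had 66795 and 63172 such tiles. Spacing thus left no clear excess between the PD1+ subsets, though it also left fewer CpGs per test. With all CpGs used, runs of at least 3 tiles numbered 3 lower and 1 higher, against 0 in the draws, in which no read spans a tile border.

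PD1+Tim3- lay close to PD1+Tim3+ rather than midway between the other subsets. Tiles were chosen on alternating CpGs as different between PD1+Tim3+ and PD1-Tim3- and measured on the remaining CpGs. In 14067 lower tiles the mean levels were 68.4% in PD1+Tim3+ (SD across tiles 18.4), 70.2% in PD1+Tim3- (SD 18.6) and 84.9% in PD1-Tim3- (SD 14.0). PD1+Tim3- thus differed from PD1-Tim3- by 89.0% of the difference of PD1+Tim3+. In 1026 higher tiles the levels were 70.8%, 68.6% and 51.6%, or 88.1% of the difference. The genome-wide differences of the PD1+ subsets, -6.30 and -7.03 points, stand in nearly the same proportion as in the lower tiles. PD1+Tim3- lay between the other subsets in 50.6% of lower and 48.0% of higher tiles, and beyond PD1+Tim3+ in 41.5% and 41.4%. With tiles divided into a left and a right part instead, it lay between them in 41.5% and 27.1%, and beyond PD1+Tim3+ in 45.4% and 49.0%. The outer subsets then also differed less. Levels in the order above were 72.2%, 73.0% and 84.1% in lower tiles and 71.7%, 71.3% and 65.4% in higher tiles. Alternating CpGs share reads, so the sets are only partly independent, and the size of the differences measured on them may be overstated.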

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

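No test was run on the values of this part, which were looked at after the main comparisons. Mitochondrial CpGs, which enter no comparison of the report, carried a methylation signal above what a count of 0 would allow, a limit that nearly any signal passes. Over 439 mitochondrial CpGs the level was 54.8% in PD1+Tim3+ at a mean depth of 164 reads, 55.6% in PD1+Tim3- at 141 reads and 63.3% in PD1-Tim3- at 111 reads. How duplicates were handled is not given in the sources used here, and nuclear copies of mitochondrial sequence and incomplete conversion of mitochondrial DNA were not tested, so these values cannot be read as the methylation of mitochondrial DNA.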

How the results depend on the processing

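The alternatives that centre tile differences, that leave out CpGs with corrected depth and that space the CpGs of named regions were chosen after the data were seen. No level, bin share or named region changed direction under any alternative run, but the balance of lower and higher tiles between the PD1+ subsets did. No paired analysis was possible because each subset has 1 library and the labels carry no replicate numbers. The alternatives fixed beforehand for promoters, gene lists and named genes were not run, since no gene annotation of hg19 was used here. Values below are given in the order PD1+Tim3+, PD1+Tim3-, PD1-Tim3- for levels, and for comparisons in the order PD1+Tim3+ against PD1-Tim3-, PD1+Tim3- against PD1-Tim3- and PD1+Tim3+ against PD1+Tim3-.

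Levels moved by more than their narrow counting intervals, with the same order of subsets each time. They were 72.5%, 72.9% and 78.9% as unweighted means, 71.7%, 72.4% and 79.1% with a coverage minimum of 3, 72.5%, 73.1% and 78.2% with a minimum of 10, and 72.5%, 72.9% and 78.9% thinned to 5 reads. The share of lower bins was 99.1%, 98.3% and 71.0% with a minimum of 3, 94.7%, 91.4% and 61.8% with a minimum of 10, and 98.8% and 63.4% in the first and last comparison when thinned.

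With a difference of 30 points, lower and higher tiles numbered 28178 and 1099, then 28432 and 1098, then 267 and 289, by construction fewer. With a coverage minimum of 10, which left 198878 tiles, they numbered 6478 and 732, 6134 and 845, and 234 and 166. With a minimum of 3, the first comparison had 101520 lower tiles over more tiles tested. Thinned to 5 reads, they numbered 4118 and 326, 4882 and 485, and 14 and 6, with fewer reads per test. With CpGs at least 200 bp apart, which left 500926 tiles, they numbered 3402 and 178, 2812 and 88, and 0 and 0. Centred on the median difference, the first comparison had 39240 lower and 4735 higher tiles and the second 4264 higher. Relative to their 100-kb bin, lower tiles numbered 27834 and 30496 in the first 2 comparisons. The share of lower among called tiles went from 95.9% to 89.2% and 87.5% in the first comparison under these 2 scalings. Between the PD1+ subsets it went from 51.0% to 48.9% and 47.2%, to 48.0% with a difference of 30 points, to 58.5% with a minimum of 10 and to 70% of the few tiles left when thinned, so the balance there depended on the setting. Other counts stayed within 1.5 times.

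With tiles divided by position into a left and a right part instead of alternating CpGs, PD1+Tim3- lay between the other subsets in 41.5% of lower and 27.1% of higher tiles. PD1+Tim3+ and PD1-Tim3- also differed less there, at 71.7% against 65.4% in higher tiles, where alternating CpGs gave 70.8% against 51.6%. The cause was not tested. Named runs and clusters kept their direction. An unadjusted Fisher's exact p under 0.05 was kept by 60 of 60 with a minimum of 3, 59 of 60 thinned, 47 of 50 with a minimum of 10 and 59 of 59 with spaced CpGs. A difference of at least 20 points, which 49 of 60 had at first since clusters include tiles that were not called, was found in 48, 46, 34 and 48 of these. The run at 16q24.1 fell from -38.7 to -18.8 points in PD1+Tim3+ with a minimum of 10. Depth limits the PD1-Tim3- library most, with a median of 7 reads at the CpGs used.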

Other observations

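The tests of bisulfite conversion, of matching for CpG number, of tile patterns over the 3 subsets and of tiles beyond called ones were chosen only after the result was seen, and the reading of the ratio of called to drawn tiles was changed after its value was known.

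Tiles that were low in one set of subsets and high in the rest were counted with limits of below 30% and above 60%. The commonest pattern was low in both PD1+ subsets and high in PD1-Tim3-, with 582 tiles against 3 in draws from one level. These tiles had mean levels of 20.4% in PD1+Tim3+ (SD across tiles 7.32), 19.9% in PD1+Tim3- (SD 6.94) and 71.7% in PD1-Tim3- (SD 7.85). The draws hold no genome-wide difference between libraries, and patterns were not counted relative to the 100-kb bin. The excess over the draws therefore does not separate these tiles from the genome-wide difference. Tiles low only in PD1-Tim3- numbered 78 against 34 in the draws, those low only in PD1+Tim3+ 14 against 5, and those low only in PD1+Tim3- 26 against 13. Tiles high only in PD1+Tim3+ numbered 3, as in the draws, and tiles high only in PD1+Tim3- 0 against 2.

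For the genome-wide higher level of PD1-Tim3-, a uniform failure of bisulfite conversion would need a rise of 24.9 points at CpG-dense tiles under 5% in PD1+Tim3+, and 0.227 was seen, which argues against it, although the mitochondrial level was higher in PD1-Tim3- as well. At 248933 CpGs with 8 to 12 reads in each library the difference was 7.73 points, which argues against the number of reads per CpG as the cause. Other traits of a shallow library were not matched. With a coverage minimum of 10, on fewer CpGs, PD1+Tim3+ and PD1-Tim3- had levels of 72.5% and 78.2%, a smaller gap than 71.8% and 78.8%. DNA of tumour or other cells cannot be told apart from a difference between T cells. The flow sort of CCR7-CD45RO+ subsets is meant to remove such DNA, but its purity is unstated. The depth ratio of 12p, an arm often gained in germ cell tumours, to 12q differed by at most 0.565% between libraries. The labels do not say whether the tumour tissue had gained 12p. Other arms departed in PD1-Tim3- relative to PD1+Tim3+, with depth ratios of 1.52 on 21p (13684 CpGs), 1.05 on 4q and 0.945 on 19p, but PD1+Tim3- lay between them, with ratios of PD1+Tim3+ to PD1+Tim3- of 0.868, 0.972 and 1.04, so this was not particular to PD1-Tim3- and its source was not tested. As a hypothesis, loss of methylation in late-replicating chromatin over cell divisions may contribute, since gpos100 bins differed from light bands by a further -3.39 points at equal PD1-Tim3- level, but only by -1.20 points when CpG number was matched as well, and G-bands stand in for replication timing, which was not measured.

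The tiles called between PD1+Tim3+ and PD1+Tim3- were weighed against sampling of reads alone. For their total this cannot be told apart: it was 0.304 times that of the shared-read draws, which are noisier than the data, while draws with independent CpGs gave only 3 lower and 4 higher tiles. Tiles starting 2 kb from a called tile, which share no short reads with it, differed in its direction by 0.853 points (95% interval over 22 autosomes 0.303 to 1.40) relative to their 100-kb bin. For tiles called in the shared-read draws the value was 0.0900 points (-0.141 to 0.321). The mean of 0.853 argues against sampling of reads alone as the source of all called tiles, but not of most of them. Of the tiles 2 kb from a tile called in the data, 51.2% went in its direction. For called tiles with no other called tile of their direction within 5 kb, the mean difference was 0.171 points (-0.228 to 0.570). That filter removes called tiles whose neighbours were called in the same direction, so a smaller value was partly built in. It cannot tell whether the difference came from groups alone, and sampling stays open for single tiles. Whether grouped differences, such as -33.3 points at 8p12 with CpGs at least 200 bp apart, may follow Tim3 or differ between any 2 sorts, through the mixture of T-cell clones for example, stays untested with 1 library per subset.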
